A study of Mus musculus with 8 samples.

How the data were processed

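Gene expression was measured in mouse alphaTC1.9 cells, a cultured line of pancreatic alpha cells derived from a glucagon-producing tumour, on Clariom S arrays, which carry short probes summarised into 1 probe set per transcript cluster. Per the labels, 4 arrays came from control cells and 4 from cells in which insulin-degrading enzyme was knocked down with a small interfering RNA, here called IDE-KD. The kind of control (untouched or given a non-targeting RNA) and the time between knockdown and harvest are not given in the sources used here. The labels call the arrays of a group biological and the RNA replicates independent, and they do not say whether the replicates came from separate cultures. The p-values therefore set a group difference against the spread between these samples, which may be in part technical. Cells grew in 16 mM glucose without further treatment, per the labels' protocols.

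The deposited values were log2 expression values, 1 column per array. The submitters' processing notes name RMA, oligo and limma without versions or roles, and RMA in its usual form corrects background, makes the distributions of all arrays equal by quantile normalization and summarises probes by median polish. A global change in RNA amount per cell would be removed by such scaling, and low signals are compressed towards the background. The values were used as deposited, with no pseudocount and no further scaling. The value table held 29129 rows. Of these, 22142 were transcript clusters and were tested, 6923 were array control rows and 64 were unplaced rows left out of the tests. The platform table gave 1 gene symbol for 19527 tested rows, several for 0 and none for 2615, which are unnamed here. Entrez identifiers of all 19527 named rows were found in the mouse gene table, and 0 symbols needed updating. These rows stood for 19494 genes, of which 33 had over 1 row. A gene with several rows was represented in gene list tests by the row with the highest mean over the 8 arrays. Coordinates are not printed because the genome build behind the probe sets is not given in the sources used here.

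The comparison was IDE-KD minus control over all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates, with Benjamini-Hochberg adjustment over the 22142 rows and a threshold of 0.05 on the adjusted p. Differences are on the log2 scale, where 1 unit is a 2-fold change. Errors of group levels are standard deviations and errors of differences are standard errors. Single values were also compared with an exact two-sided permutation test of the 8 values, whose smallest possible p for 4 against 4 arrays is 0.0286. The number of arrays limits the precision: the median half-width of the 95% confidence interval of a log2 difference was 0.32.

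Before the data were examined, 29 gene lists with 1252 entries were fixed from textbook knowledge of alpha cells, insulin-degrading enzyme and cultured cells, among them markers of other islet, stromal, immune, endothelial and exocrine cells. Of the entries, 1133 were measured and 119 had no match among the named rows and were not analysed here. The lists were tested with camera in limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and beside it with a correlation estimated from the data and with fry. Each list's median was also placed among the medians of 10000 random lists of the same size drawn from the same 20 bins of expression level. Such random lists do not carry the correlation among a list's members, so these percentiles can be too extreme. Reactome mouse pathways shipped with fgsea 1.28.0 that had 15 to 300 measured members were tested in the same way. The naming rule, also fixed beforehand, took Ide, Gcg, Ins1, Ins2, Sst and a few further genes whatever their values, the 12 genes with the largest rise and the 12 with the largest fall past the threshold with no overlap of the groups, and up to 4 members of each list past the threshold. Where too few genes passed, the places were filled with the smallest p values, and a list without a passing member contributed 2 members, as values only. Predicted genes, clone names and olfactory or vomeronasal receptors were not named. Members of a Reactome pathway were to be named only past the threshold. Ins1 was not analysed here because no named row carried its symbol, and the further genes of that rule and 1 of the gene lists are not reported here.

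The limma and camera steps were tested on simulated data with the control means and limma's moderated variances of these 22142 rows, drawn independently without any structure between arrays, with 4 arrays against 4 and 200 rows changed by mixed fold sizes, over 20 rounds. At an adjusted p under 0.05, limma called 42.2% of simulated 1.5-fold changes, 97.5% of 2-fold changes and 100% of 3-fold changes, 5.40% of all calls were false, and 95.0% of the 95% intervals held the true change. Of 20 rounds without any change, 2 called at least 1 row. Shifting the S phase list by 0.1 on the log2 scale led camera to call it in 95% of rounds.

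Alternatives planned beforehand were quantile normalization of the tested rows again, array medians subtracted, cyclic loess, 2 filters on dim rows, rows with 1 gene symbol only, eBayes with trend and robust settings, array weights, other thresholds and limma's treat against a 1.2-fold change, the other set tests, the mean of a gene's probe sets, the replicate number as a block, and each array left out in turn. Leaving out IDE-KD arrays 1 and 3 together, the standard deviation of each array as a covariate, the odd or even replicate number as a factor, and fits of the odd-numbered or even-numbered arrays alone were added after the data were seen. All 8 value columns matched a sample, so 0 columns were set aside. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.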

Results

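Expression of 19494 named genes was measured in alphaTC1.9 cells, a mouse pancreatic alpha cell line, on 4 arrays of control cells and 4 arrays of IDE-KD cells, in which the mRNA of insulin-degrading enzyme, a zinc metalloprotease that cleaves insulin and other small peptides, had been targeted. The deposited values were log2 expression values, for which the submitters' processing notes name RMA, and their medians over the tested probe sets lay between 5.10 and 5.17 on the 8 arrays. Correlations between arrays of one group ranged from 0.984 to 0.993 and those between groups from 0.984 to 0.991. The single comparison the design implies asks which transcripts differ between knockdown and control alpha cells.

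Ide itself (probe set TC1900001454.mm.2) was lower in every IDE-KD array than in every control array. Its level was 8.62 ± 0.10 (SD, n = 4) in control cells and 8.01 ± 0.11 (SD, n = 4) in IDE-KD cells, a log2 difference of -0.62 (SE 0.12, 95% confidence interval -0.87 to -0.36), or 1.53-fold lower. The control arrays read 8.66, 8.62, 8.72 and 8.48, and the IDE-KD arrays 7.91, 8.14, 7.92 and 8.05. The exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 arrays allow. In limma the unadjusted p for Ide was 0.000164, rank 3 of 22142 and the first among lower rows, but the adjusted p over all rows was 1.00, while adjusted over the list alone it was 0.0072 within insulin and IGF signaling and 0.0046 within peptide-degrading metalloproteases and aminopeptidases. Among odd-numbered arrays alone Ide differed by -0.78 (SE 0.16) and among even-numbered arrays alone by -0.45 (SE 0.17), and the interaction of -0.33 (SE 0.21) lay less than 2 standard errors from 0.

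**Figure D1:**
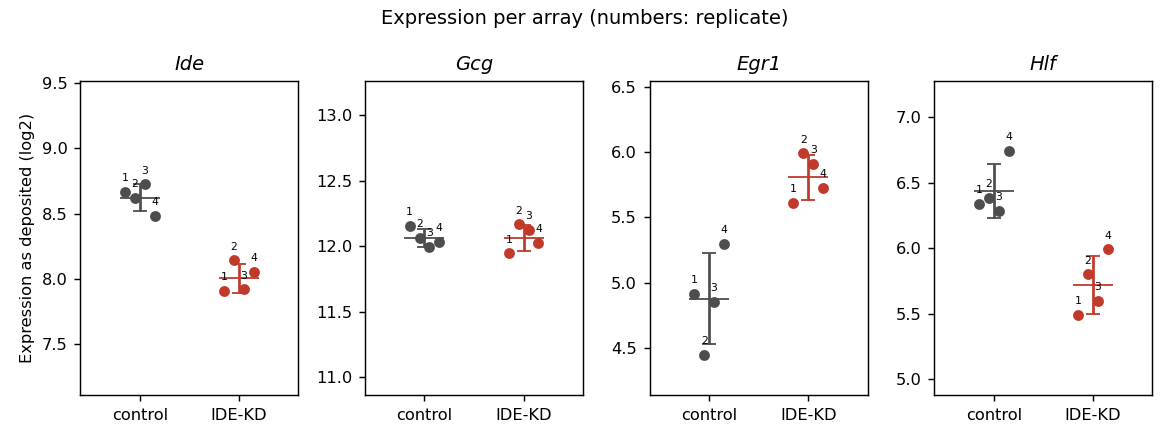
Deposited log2 expression (vertical axis) of Ide, Gcg, Egr1 and Hlf on each array, with the 4 control arrays in grey and the 4 IDE-KD arrays in red; points carry their replicate number, and bars show the group mean and SD. The 4 Ide values of IDE-KD cells, 7.91 to 8.14, lie below the lowest control value of 8.48, whereas both groups average 12.06 for Gcg.

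Glucagon mRNA did not differ detectably, with Gcg, which encodes the hormone precursor that defines alpha cells, at 12.06 ± 0.07 (SD, n = 4) in control and 12.06 ± 0.10 (SD, n = 4) in IDE-KD cells. The 95% confidence interval of its log2 difference ran from -0.24 to 0.25, with an exact two-sided permutation p of 0.943. Of other islet hormones, Ins2, an insulin gene, was near the median array control row of 4.56 and Sst, which encodes somatostatin, above it. The array control rows include 1324 exon and 5222 intron rows. The median intron row stood at 4.16, so 4.56 marks a low signal and not the background itself. Ins2 read 4.61 ± 0.46 and 4.87 ± 0.29 in control and IDE-KD cells (SD, n = 4), and Sst read 5.49 ± 0.33 and 5.64 ± 0.15 (SD, n = 4). The log2 differences of 0.25 (SE 0.21) for Ins2 and 0.15 (SE 0.16) for Sst were within the spread between replicates. Leaving out 1 array gave 0.12 (without control replicate 2) to 0.45 (without control replicate 1) for Ins2 and as little as -0.015 for Sst (without control replicate 4).

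Over all 22142 probe sets, limma found 0 higher and 0 lower in IDE-KD cells at an adjusted p under 0.05, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 1017 rows, 595 higher and 422 lower, against 1107.1 expected by chance. The groups did not overlap at 620 rows, 2.80% of those tested, where chance gives 2.86%. The count at the adjusted threshold was also 0 with limma's treat, with array weights, with eBayes set to trend and robust, and with each array left out in turn. The 95% confidence interval excluded a 2-fold change at 22074 rows (99.7%) and a 1.5-fold change at 18503 rows (83.6%). A fitted change of at least 1.5-fold was seen at 42 rows, and of at least 2-fold at 0.

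**Figure D2:**
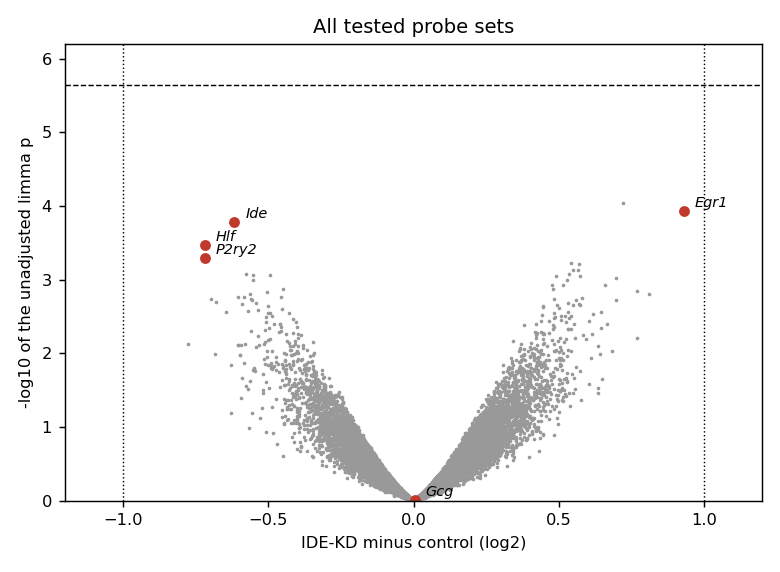
Log2 difference between IDE-KD and control cells (horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for the 22142 tested probe sets, with 5 genes marked in red. Dotted lines mark 2-fold changes and the dashed line the p at which the smallest p of all rows would pass the adjusted threshold; 0 rows lie beyond either.

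The genes with the smallest p values are therefore given as values. Among those higher in IDE-KD cells, Egr1, an immediate-early transcription factor gene, had the largest fitted difference, 0.93 (SE 0.17, 95% confidence interval 0.56 to 1.30), with 4.88 ± 0.35 in control and 5.81 ± 0.17 in IDE-KD cells (SD, n = 4). The next were Lmod2 at 0.54 (SE 0.12), Kash5 at 0.57 (SE 0.13), Tmem247 at 0.55 (SE 0.12), Aadacl2fm3 at 0.56 (SE 0.13), Nr1h4, the bile acid receptor gene FXR, at 0.70 (SE 0.16) and Pcp4 at 0.53 (SE 0.12). Hapln1, whose product links hyaluronan and proteoglycans, read 0.66 (SE 0.16), the cation channel gene Trpv4 0.48 (SE 0.11), Inhba, which encodes an activin subunit, 0.48 (SE 0.12), Prdm6 0.81 (SE 0.20) and Il24 0.58 (SE 0.15). Of these 12 genes, 10 had control levels below the median array control row of 4.56; Egr1, at 4.88, and Hapln1, at 6.06, were above it.

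On the lower side, Ide was followed by Hlf, a transcription factor gene of the PAR bZIP family with circadian expression in many tissues, at -0.72 (SE 0.15), from 6.44 ± 0.21 to 5.72 ± 0.22 (SD, n = 4). The nucleotide receptor gene P2ry2 differed by -0.72 (SE 0.15), from 4.64 to 3.93. Rhoj read -0.58 (SE 0.13), Odr4 -0.50 (SE 0.11), Spopl -0.55 (SE 0.13), Atp13a4 -0.55 (SE 0.13) and Nfic, a nuclear factor I gene, -0.45 (SE 0.11). Ttll3, a tubulin glycylase gene, read -0.50 (SE 0.12), Sparcl1 -0.56 (SE 0.14), Stc2, which encodes stanniocalcin, -0.58 (SE 0.15) and Akna -0.60 (SE 0.15). All of these genes kept the 2 groups apart, with an exact two-sided permutation p of 0.0286 each, as 620 rows did. Both group levels of Atp13a4 (3.08 and 2.53), Stc2 (3.81 and 3.23) and Akna (4.06 and 3.46) lay below the median array control row of 4.56. The IDE-KD levels of P2ry2 (3.93) and Rhoj (4.09) lay below it as well.

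The alpha cell programme showed no shift past the threshold. Of 18 measured genes of the alpha cell identity list, 9 were higher and 9 lower, with a median of -0.0066 and a mean of 0.04 (camera adjusted p = 0.738). Its members with the smallest p were Mlxipl, the ChREBP gene, at 0.45 (SE 0.16) and Tm4sf4 at 0.22 (SE 0.13). In the pan-endocrine program, 18 of 27 genes were lower (median -0.05, adjusted p = 0.0707), with Foxa1 at -0.42 (SE 0.15) and the neuropeptide precursor gene Vgf at -0.39 (SE 0.14). The mean over its members relative to the control mean was -0.06, -0.03, -0.14 and -0.09 on IDE-KD arrays 1, 2, 3 and 4. Control arrays lay between -0.02 and 0.04, above all of these. Camera with an estimated correlation gave this list an adjusted p of 0.879. Alpha cell electrical activity and nutrient sensing had 20 higher and 22 lower members (median -0.0033, adjusted p = 0.475), with the somatostatin receptor gene Sstr2 at 0.38 (SE 0.13) and the hexokinase gene Hk2 at -0.29 (SE 0.12). Exocytosis machinery had 24 higher and 23 lower members (median 0.0031, adjusted p = 0.769; camera gave the direction as lower), with Stx7 at -0.29 (SE 0.14) and Stxbp3 at 0.27 (SE 0.14, and 0.16 without IDE-KD replicate 4). Adjusted over the list alone, 0 members of these 4 lists passed, as over all rows.

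Lists around the targeted enzyme held 1 gene that passed adjusted over the list alone, Ide. Insulin and IGF signaling had 16 higher and 28 lower members (median -0.02, adjusted p = 0.475), where Ide alone passed adjusted over the list alone and Trib3, a pseudokinase gene, was at -0.25 (SE 0.12). Peptide-degrading metalloproteases and aminopeptidases had 9 higher and 19 lower members (median -0.05, adjusted p = 0.23), again with Ide alone passing adjusted over the list alone and the dipeptidyl peptidase gene Dpp9 at -0.27 (SE 0.12). Neither list held a member past the threshold over all rows.

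Markers of other cell types did not shift as groups. Beta, delta, PP and epsilon cell markers had 15 higher and 6 lower members (median 0.04, adjusted p = 0.673), with Nkx6-1, a beta cell transcription factor gene, at -0.30 (SE 0.14) and Hhex, a delta cell one, at 0.30 (SE 0.18, and 0.19 without control replicate 2). Fibroblast and stellate cell markers had 12 higher and 6 lower (median 0.10, adjusted p = 0.297), with Lum at 0.30 (SE 0.13) and Thy1 at 0.31 (SE 0.15). Immune, endothelial and exocrine cell markers had 11 higher and 7 lower (median 0.06, adjusted p = 0.769). In that list 2 genes passed adjusted over the list alone, in opposite directions, each with an adjusted p of 0.034 over the list alone and 0.0286 in the exact test: the VEGF receptor gene Kdr differed by -0.40 (SE 0.11), from 8.87 to 8.47, and the T cell receptor complex gene Cd3e by 0.44 (SE 0.12), from 2.92 to 3.36, a level below the median array control row. Adjusted over all rows neither gene passed, with ranks of 76 for Kdr and 61 for Cd3e among 22142. The adjustment over the list alone does not correct across the 29 lists. The fry test for change in either direction gave this list an adjusted p of 0.0337.

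Immediate-early genes were split, with 14 higher and 15 lower of 29 measured (median -0.0041, mean 0.05, camera adjusted p = 0.36). Egr1 was the 1 member to pass adjusted over the list alone (adjusted p = 0.0034), though not over all rows, and Fos, another immediate-early transcription factor gene, read 0.31 (SE 0.12). The fry test for change in either direction gave an adjusted p of 0.0337. NF-kB and inflammatory response had 22 higher and 10 lower (median 0.06, adjusted p = 0.36), with Ier3 at -0.44 (SE 0.15) and Cxcl2 at 0.40 (SE 0.16, and 0.26 without IDE-KD replicate 4), and type I interferon response had 23 higher and 19 lower (median 0.03, adjusted p = 0.36), with Gbp2 at 0.37 (SE 0.14) and Rsad2 at -0.33 (SE 0.16).

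Microtubule and ciliary genes did not pass either. Tubulins and microtubule regulators had 25 higher and 35 lower members (median -0.03, adjusted p = 0.23). The lowest fitted difference of any tested row belonged to one of them, Stmn4, a microtubule-destabilising stathmin gene, at -0.78 (SE 0.24), but it was -0.48 without IDE-KD replicate 3, and both group levels, 3.76 and 2.98, lay below the median array control row of 4.56. Clip1, whose product binds microtubule ends, was at -0.29 (SE 0.12). Primary cilium genes had 31 higher and 41 lower (median -0.02, adjusted p = 0.62), with B9d2 at 0.40 (SE 0.15, and 0.26 without control replicate 1) and Ahi1 at 0.35 (SE 0.14). TGF-beta, adhesion and extracellular matrix had 26 higher and 24 lower (median 0.0018, adjusted p = 0.769; camera gave the direction as lower), with the laminin gene Lamb1 at -0.58 (SE 0.20) and Timp1 at -0.40 (SE 0.17). Both group levels of Timp1 (3.38 and 2.98) lay below the median array control row.

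Stress and protein turnover lists were likewise not past the threshold. The integrated stress response list of ATF4 targets had 9 higher and 29 lower members (median -0.07, percentile 0.65 of 10000 random lists matched on level, camera adjusted p = 0.102), with Stc2 at -0.58 (SE 0.15) and the serine synthesis gene Psph at 0.40 (SE 0.13). Stc2 lay below the median array control row in both groups. The matched lists do not carry the members' correlation, and camera with an estimated correlation gave an adjusted p of 0.879. The ATF6 and XBP1 arms of the unfolded protein response had 14 higher and 18 lower (median -0.01, adjusted p = 0.51), with Atf6 at -0.21 (SE 0.12) and P4hb at -0.19 (SE 0.13). Heat shock response had 13 higher and 9 lower (median 0.01, adjusted p = 0.769; direction lower by camera), with Hspb1 at 0.46 (SE 0.18) and Hspa4 at -0.16 (SE 0.12, and -0.10 without control replicate 3). Hspb1 (3.03 and 3.49) lay below the median array control row in both groups. Autophagy and lysosome had 20 higher and 27 lower (median -0.02, adjusted p = 0.297), with Nbr1, an autophagy receptor gene, at -0.35 (SE 0.14, and -0.22 without IDE-KD replicate 3) and Neu1 at -0.24 (SE 0.11). Proteasome had 21 higher and 21 lower (median 0.0042, mean -0.0078, adjusted p = 0.738), with Psmb3 at -0.23 (SE 0.13) and Psmc5 at -0.21 (SE 0.15, and -0.13 without IDE-KD replicate 1 or -0.32 without IDE-KD replicate 2). Adjusted over the list alone, 0 members passed in any of these 5 lists, nor in the 3 microtubule, cilium and matrix lists, the NF-kB and interferon lists, or the lists of beta, delta, PP, epsilon, fibroblast and stellate cell markers.

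Metabolic lists gave small medians. Oxidative phosphorylation had 32 higher and 42 lower members (median -0.01, adjusted p = 0.359), with Atp5e at -0.27 (SE 0.16, and -0.13 without control replicate 2) and Cox7a2 at -0.18 (SE 0.13, and -0.084 without IDE-KD replicate 1). Glycolysis had 11 higher and 15 lower (median -0.04, adjusted p = 0.36), with Hk2 at -0.29 (SE 0.12) and the pyruvate dehydrogenase kinase gene Pdk1 at 0.28 (SE 0.16). Hypoxia response had 10 higher and 15 lower (median -0.02, adjusted p = 0.475), with Vegfa at -0.37 (SE 0.14) and again Pdk1. Cholesterol and fatty acid synthesis had 20 higher and 9 lower (median 0.05, adjusted p = 0.361), with the squalene synthase gene Fdft1 at 0.20 (SE 0.14, and 0.11 without IDE-KD replicate 4) and the fatty acid synthase gene Fasn at -0.21 (SE 0.14, and -0.13 without IDE-KD replicate 3). That median lay at percentile 99.9 of 10000 random lists matched on level, which do not carry the correlation among members. Camera with an estimated correlation gave an adjusted p of 0.879. Adjusted over the list alone, 0 members of these 4 lists passed.

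Of the 29 lists, 2 passed with camera, both lower in IDE-KD cells, the S phase genes of the cell cycle and the cytosolic ribosomal protein genes. Both calls were lost with an estimated correlation (adjusted p = 0.879 each), and the directional fry test called 0 lists (smallest adjusted p = 0.873). In the S phase list 44 of 52 genes were lower (median -0.09, adjusted p = 0.0012), among them Hells, a chromatin remodeller gene, at -0.38 (SE 0.15) and Exo1, a DNA exonuclease gene, at -0.30 (SE 0.13). In the ribosomal list 38 of 52 genes were lower (median -0.06, adjusted p = 0.042), with Rps19 at -0.27 (SE 0.14) and Rpl27 at -0.28 (SE 0.16, and -0.14 without IDE-KD replicate 3). Both calls were also lost after quantile normalization of the tested rows again and after cyclic loess, and the ribosomal call with array weights, after subtracting array medians and with either filter on dim rows. Cell cycle genes of the G2 and M phases had 22 higher and 34 lower members (median -0.05, adjusted p = 0.123), with Cdca8 at -0.25 (SE 0.11) and Kif20a at -0.26 (SE 0.12), and cell cycle inhibitors and p53 targets had 15 higher and 17 lower (median -0.02, mean 0.02, adjusted p = 0.769), with Plk3 at -0.50 (SE 0.18; -0.32 without IDE-KD replicate 3) and the cyclin gene Ccng1 at 0.48 (SE 0.20; 0.30 without IDE-KD replicate 2). Adjusted over the list alone, 0 members of these 4 lists passed.

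The lowest S phase and ribosomal values were those of IDE-KD arrays 1 and 3. These arrays also had the smallest SD over the tested rows, 2.16 and 2.13, against 2.20 to 2.25 on the other arrays. Their means of the exon control rows were the lowest too, 6.95 and 6.92, against 7.05 to 7.13. So were their means of the intron control rows, 4.20 and 4.20, against 4.25 to 4.38. Their exon minus intron contrasts, 2.76 and 2.72, were therefore near those of control arrays 1 and 3, 2.74 and 2.71. As the mean over members relative to the control mean, the S phase list stood at -0.20 and -0.22 on IDE-KD arrays 1 and 3 and at 0.07 and -0.02 on arrays 2 and 4, with control arrays between -0.02 and 0.02. The ribosomal list stood at -0.36, 0.18, -0.18 and 0.09 on IDE-KD arrays 1, 2, 3 and 4, with control arrays between -0.08 and 0.11. Oxidative phosphorylation moved with it, at -0.35, 0.26, -0.15 and 0.14, and so did the proteasome list, at -0.25, 0.22, -0.15 and 0.15. Within odd-numbered arrays the medians were -0.19 for S phase and -0.20 for ribosomal genes, and within even-numbered arrays 0.02 and 0.09. The count of 2 lists became 0 without IDE-KD replicate 1 or without IDE-KD replicate 3, 1 without control replicate 2 or without control replicate 4, 5 without IDE-KD replicate 4 and 6 without IDE-KD replicate 2, and it was 4 higher and 0 lower without IDE-KD arrays 1 and 3 together and 3 higher and 0 lower with array SD as a covariate.

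**Figure D3:**
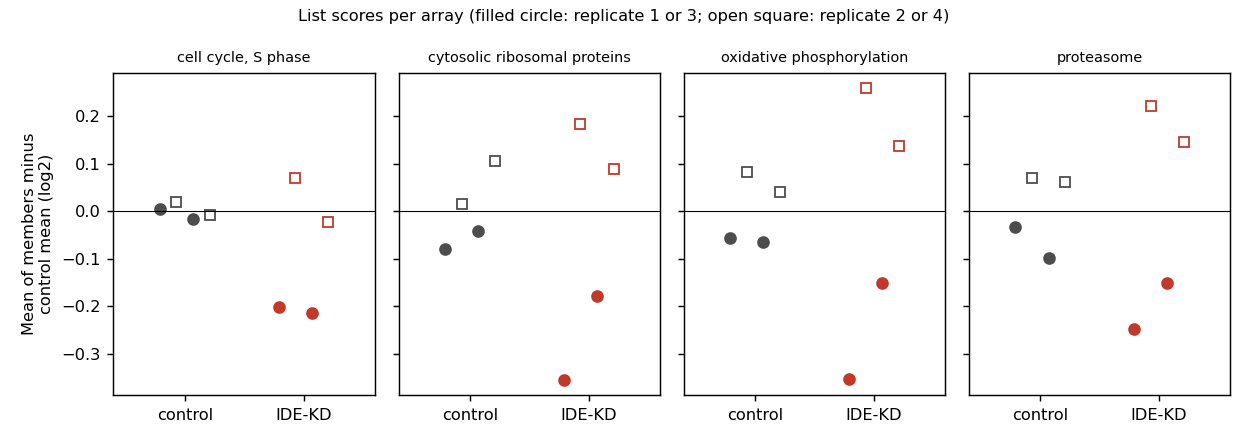
Mean log2 expression of list members on each array relative to the control mean (vertical axis) for 4 gene lists, with control arrays in grey and IDE-KD arrays in red; filled circles are replicates 1 and 3, open squares replicates 2 and 4. For S phase genes the filled IDE-KD circles lie at -0.20 and -0.22, below all other arrays, and the open squares at 0.07 and -0.02.

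Among 701 Reactome pathways, camera called 8 higher and 46 lower in IDE-KD cells, and 0 with an estimated correlation (smallest adjusted p = 0.998). The higher ones with the smallest p were collagen formation (63 genes, median 0.15, adjusted p = 0.0102), collagen degradation (57 genes, median 0.15, adjusted p = 0.0102), collagen biosynthesis and modifying enzymes (54 genes, median 0.15, adjusted p = 0.0111) and the assembly of collagen fibrils (37 genes, median 0.16, adjusted p = 0.0157). The lower ones were led by formation of a pool of free 40S subunits (71 genes, median -0.07), mitotic prometaphase (96 genes, median -0.06), nonsense-mediated decay independent of the exon junction complex (66 genes, median -0.07) and mitotic G2 and G2/M phases (92 genes, median -0.08), each with an adjusted p of 0.019. Over all tested rows the difference was lower at higher expression levels (Spearman correlation -0.20). The median over members of the gene's mean level was 4.60, 4.09, 4.72 and 4.29 in these collagen pathways. It was far higher in the lower pathways, 9.21, 7.63, 9.28 and 7.39. These 8 pathways each had an adjusted p of 0.998 with an estimated correlation, and no member passed the threshold. After quantile normalization of the tested rows again the split was 5 higher and 0 lower, after cyclic loess 4 higher and 0 lower, and with array SD as a covariate 10 higher and 2 lower. The balance turned without IDE-KD arrays 1 and 3 together, to 132 higher and 11 lower. The count of 54 became 88 without control replicate 1, 0 without control replicate 2, 24 without control replicate 3, 0 without control replicate 4, 24 without IDE-KD replicate 1, 196 without IDE-KD replicate 2, 0 without IDE-KD replicate 3 and 93 without IDE-KD replicate 4.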

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

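Of the tests in this part, those of single far arrays, the splits at an unadjusted p, for lists and for pathways, the cyclic loess fit and the simulated power were chosen before the results were seen, and the others, together with the fits of odd-numbered and even-numbered arrays and the fit without IDE-KD arrays 1 and 3, were chosen afterwards. In 6 of 168 groups of 4 arrays, 1 array stood apart from the other 3, measured as its gap to the nearest divided by the range, where chance gives 8.4. Sst read 5.0 on control array 4 against 5.64 to 5.66 on the others (ratio 0.967). Atp13a4 read 3.21 on control array 3 against 3.04 to 3.05 (ratio 0.915). Kif20a read 8.74 on control array 1 against 8.90 to 8.93 (ratio 0.831). Mlxipl read 3.86 on IDE-KD array 2 against 4.46 to 4.48 (ratio 0.964). Cd3e read 3.20 on IDE-KD array 2 against 3.4 to 3.44 (ratio 0.858). Cxcl2 read 3.75 on IDE-KD array 4 against 3.18 to 3.22 (ratio 0.931). Among 6987 control and unplaced rows outside the comparison, limma found 0 past the threshold (smallest adjusted p = 0.464).

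The first pattern is the absence of any gene past the threshold. With a real count of 0, the 35 of 35 splits of the 8 arrays into 4 and 4 with at least as many genes (highest other 0) decide nothing. Chance cannot be excluded for the rows at an unadjusted p under 0.05, since 18 of 35 splits gave at least the real 1017 (highest other 3501), and 5 of the 18 splits with 2 odd and 2 even replicate numbers on each side (highest other 1198). Whether too few arrays hid a 2-fold change is not decided by the simulation, in which 97.5% of such changes were called. It changed 200 rows at once, without structure between arrays, and the adjusted threshold is stricter where fewer rows change. A lone 2-fold change may therefore have gone uncalled. Taken row by row, the 95% confidence interval excluded a 2-fold change at 22074 rows (99.7%). Only 42.2% of simulated 1.5-fold changes were called, so changes of about the size of Ide may have been missed. The split with 3501 rows sets odd against even replicate numbers, with 2 control and 2 IDE-KD arrays on each side. Whether this structure is apart from the knockdown is not decided. First principal component values of replicates 1 to 4 were -5.47, 18.0, -2.37 and 8.85 in control cells. They lay further apart in IDE-KD cells, at -25.1, 19.9, -29.3 and 15.4. For the interaction of knockdown and odd or even number limma called 0 rows. Camera called oxidative phosphorylation (adjusted p = 3.8e-10), but not with an estimated correlation (adjusted p = 0.642). With the odd or even number as a factor limma called 0 genes (1387 rows at an unadjusted p under 0.05), as it did within odd-numbered arrays alone (1811 rows) and within even-numbered arrays alone (1251 rows).

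The next pattern is the lower S phase and ribosomal lists, for which chance cannot be excluded, since 22 of 35 splits gave at least the real 2 lists (highest other 14, the split of odd against even numbers) and 16 of 35 at least the real 54 Reactome pathways (highest other 279), as did 8 and 4 of the 18 splits balanced for odd and even numbers. A trend with expression level had a Spearman correlation of -0.20 between difference and level. The 2 medians lay at percentiles 0.03 and 0.32 among random lists matched on level. Those lists draw unrelated genes, while the members were correlated (estimated at 0.23 for S phase and 0.66 for ribosomal genes). The percentiles therefore do not decide whether the trend is the whole cause. A part of the shift may follow it. Cyclic loess moved the S phase median from -0.09 (quartiles -0.17 and -0.028) to -0.067 (-0.15 and 0.00024). It moved the ribosomal median from -0.06 (-0.12 and 0.0047) to -0.036 (-0.098 and 0.024). Both calls were lost after cyclic loess (camera adjusted p = 0.0982 and 0.366). A knockdown effect shared by all 4 arrays stays open: the highest IDE-KD scores, 0.070 for S phase and 0.18 for ribosomal genes, lay above the highest control scores of 0.018 and 0.11, which met the bound written for this test, but both were those of IDE-KD array 2, and 1 array excludes nothing. Leaving out IDE-KD arrays 1 and 3 gave medians of 0.038 and 0.16, but these arrays were picked for their low scores, so this decides nothing; with the odd or even number as a factor both lists passed (adjusted p = 0.0011 and 0.0233) but not with an estimated correlation (adjusted p = 0.807 and 0.815), and the interaction of knockdown and odd or even number passed in camera for both (adjusted p = 0.000124 and 7.1e-07) but not with an estimated correlation (adjusted p = 0.413 and 0.642). Array signal quality is a candidate source of the odd and even structure, since the exon minus intron contrast of the array control rows reached at most 2.76 on odd-numbered arrays and at least 2.78 on even-numbered ones (exact permutation p = 0.0286, the smallest possible), and a stronger knockdown behind IDE-KD arrays 1 and 3 stays open, since the Ide interaction with odd or even number, -0.33 (SE 0.21), lay less than 2 standard errors from 0.

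The last pattern is the higher Egr1 in IDE-KD cells. Chance stays open, because 2.59 rows with a p as small are expected among all tested and 2 were seen. A general immediate-early response, as handling or serum might give, stays open: the median of the other immediate-early genes, -0.0052, lay at percentile 59.5 of matched random lists, but the members went both ways, and Fos read 0.31 with all IDE-KD arrays above all control arrays. IDE-KD arrays 1 and 3 do not carry it, because 105% of the difference remained without them (0.98). An effect of the knockdown on Egr1 may be followed up as a hypothesis, with chance not excluded.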

How the results depend on the processing

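The alternatives without IDE-KD arrays 1 and 3, with array SD as a covariate, and those by odd or even replicate number were chosen after seeing the data; the rest were planned. Under all 22 alternatives Ide stayed lower, from -0.78 to -0.45, with unadjusted limma p from 6.8e-06 to 0.0267 and adjusted p from 0.152 to 1.00, and the counts of higher and lower genes stayed 0. Of 1660 alternative values of 78 other named genes, 0 passed and 8, in 3 genes, changed sign; in 18 of these genes leaving out 1 array moved the value by over 1.5 times. Of 693 alternative list values, 40 changed their call and 142 their sign.

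Lists and Reactome pathways past the threshold numbered 0 and 5 after quantile normalization again, 0 and 4 after cyclic loess, 1 and 1 without rows below the median control row, 1 and 4 without the dimmer rows, 1 and 0 with array weights, and 0 and 0 with an estimated correlation. Lists numbered 1 after subtracting array medians and 0 by fry's directional test (2 by its test for change in either direction). Leaving out 1 array gave 0 to 6 lists and 0 to 196 pathways. With the median of the ribosomal list at -0.06 and of the proteasome list at 0.0042 over all arrays, leaving out 1 array gave ranges of -0.16 to 0.049 and -0.081 to 0.087. Without IDE-KD arrays 1 and 3 there were 4 lists, all higher, and 143 pathways, 132 higher and 11 lower, with medians of 0.038 for S phase, 0.21 for oxidative phosphorylation and 0.16 for ribosomal genes; of the 54 pathways, 6 were shared in the same direction. With array SD as a covariate the direction turned, with 3 lists higher and 0 lower and 12 pathways, 10 higher and 2 lower, and with oxidative phosphorylation at 0.10 and ribosomal genes at 0.052. Odd-numbered arrays alone gave 6 lists, all lower, and 211 pathways, 16 higher and 195 lower (proteasome -0.13), and even-numbered arrays alone 1 list, higher, and 39 pathways, 21 higher and 18 lower (S phase 0.024, oxidative phosphorylation 0.17, ribosomal 0.086). The cause was not tested beyond fewer rows or arrays. With the replicate block there were 0 genes, 2 lists and 50 pathways, and Ide was at -0.62. Correlations of deviations between arrays of the same number were 0.10, 0.13, 0.0876 and 0.0985. Only control array 4 and IDE-KD array 2 correlated best with their own number. Control arrays 1, 2 and 3 correlated best with IDE-KD arrays 3, 4 and 1 (0.17, 0.21 and 0.16). Dim genes are limited by low signal: 9526 tested rows lay below the median array control row. That row is not a background level, since the median intron control row, at 4.16, was lower.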

Other observations

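The comparisons of odd with even replicate numbers in this part were chosen after seeing that the first principal component (29.2% of the variance) placed the odd-numbered arrays between -29.3 and -2.37 and the even-numbered ones between 8.85 and 19.9. Each side held 2 control and 2 IDE-KD arrays. With the group in the fit, limma called 0 rows between odd and even arrays (smallest adjusted p = 0.0935), with 3529 at an unadjusted p under 0.05, against 1387 between knockdown and control in the same fit. Because the odd and even split was picked for parting the arrays on that component, its larger count does not rank the contrasts. Camera called 14 of the 29 lists, and 0 with an estimated correlation. Oxidative phosphorylation (median -0.27), cytosolic ribosomal (-0.26) and proteasome genes (-0.28) were lower on odd-numbered arrays, as were glycolysis (-0.14), hypoxia response (-0.19) and both cell cycle lists (-0.12 for S phase and -0.13 for G2 and M phases). The S phase gap was seen in IDE-KD cells only. Mean S phase scores were 0.0051 and -0.016 on control arrays 1 and 3 and 0.018 and -0.0078 on control arrays 2 and 4. They were -0.20 and -0.22 on IDE-KD arrays 1 and 3 and 0.07 and -0.02 on IDE-KD arrays 2 and 4. Beta, delta, PP and epsilon cell markers were higher there (0.22). The adjusted p of oxidative phosphorylation and of ribosomal genes was 0.291 with an estimated correlation, and that of the proteasome 0.257.

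Some of the genes with a small p between odd and even arrays are given as values. They were selected after they were seen and not by rank, so genes with a smaller p than some of them are left out. Iapp, which encodes islet amyloid polypeptide, a substrate of insulin-degrading enzyme, read 3.23 on odd and 4.25 on even arrays, a log2 difference of -1.02 (SE 0.17, limma adjusted p = 0.121), and both levels lay below the median array control row of 4.56, so the size is uncertain, as it is for Igtp (3.69 and 4.53) and Wipf1 (4.25 and 3.39). Igtp, an interferon-inducible GTPase gene, differed by -0.84 (SE 0.12), Upp1 by -0.67 (SE 0.11), Mrpl14, a mitochondrial ribosomal protein gene, by -0.79 (SE 0.13) and Gins1, a DNA replication gene, by -0.78 (SE 0.14). Higher on odd arrays were Wipf1 at 0.85 (SE 0.12), the neurotrophic factor gene Nrtn at 0.85 (SE 0.12), the zinc transporter gene Slc30a3 at 0.73 (SE 0.11), and the peptide precursor genes Prlh at 0.74 (SE 0.13) and Pdyn at 0.67 (SE 0.13).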
